A study of Homo sapiens with 42 samples.

How the data were processed

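Messenger RNA was sequenced from human pulmonary fibroblasts (HPF), primary cells grown in culture and serum starved before cytokines were added. The 42 samples formed 14 groups of 3 replicates in 2 batches named in the labels. The labels gave doses of 50 ng/ml LIGHT (TNFSF14, a ligand of the lymphotoxin beta receptor), 25 ng/ml IL-13, 100 ng/ml IL-17A and 5 ng/ml TGFβ. RNA was isolated with a column kit and poly(A) RNA was made into directional libraries. Per the submitters' processing notes, Bowtie 1.1.2, STAR 2.6.1 and featureCounts 1.6.5 were used with the human genome build GRCh38. Other settings of alignment and counting, strand included, were not given in the sources used here.

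The deposited table held counts of reads per gene, with no normalization, for 58347 rows and 41 libraries, and 0 of its sample columns were left unused. The group with IL-17A for 24 h had a column for 2 of its 3 replicates, so its n was 2. Of the row identifiers, 55720 were in GENCODE release 29 with their version and 58084 without it. Symbols were those of the deposited row names, and 51851 of them equalled the symbol of that release for the same identifier. Reads of paralogs and of genes that overlap on opposite strands could not be separated from the table. Total counts ran from 26541622 to 36955280 per library in batch 1 (17 libraries) and from 19308634 to 32719430 in batch 2 (18 libraries). Replicates were checked for copies of each other through the variance of paired counts, at least 20 reads per pair, and the ratio to counting noise was 2.08 to 39.3 over 40 pairs. Residuals of libraries with the same replicate number correlated at 0.06 at most across genes, which are not independent replicates, so samples were treated as unpaired.

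The 6 columns of the TGFβ groups did not line up with the row names. They filled 36484 rows and left 21863 empty, and ACTB, among the most abundant transcripts, had 2 to 30 reads in them against 112020 to 204214 in the other libraries. Libraries were compared with the mean log2 count of PBS for 24 h, over 11098 filled rows where that mean stood for over 100 reads. Each of the 6 correlated with it at 0.07, while the other libraries did so at 0.89 or more. Over all rows they filled, the 6 correlated with each other at 0.97 or more. No gene was therefore named in them, the comparisons of TGFβ with PBS and the LIGHT by TGFβ interaction were not run, and LIGHT after TGFβ was compared with TGFβ alone on unnamed rows. As a result the fit of batch 1 held 17 libraries in 6 groups and that of both batches 35 libraries in 12 groups, fewer than planned.

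Each comparison was tested with edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr by group, scaled by TMM and fitted with a mean per group (glmQLFit, robust), followed by the quasi-likelihood F test. Benjamini-Hochberg adjustment covered all genes tested, with a threshold of 0.05. The fits tested 17588 genes in batch 1, 16521 in batch 2 and 18239 over both. The standard error of a log2 fold change was its size over the square root of F. Group levels are given in CPM, the usual count scaled to library size, here by TMM, as mean and SD. Comparisons across batches were differences of effects within batches, except PBS 96 h against PBS 24 h, in which batch and time could not be separated. Folds against a group with 0 reads used a floor of 3 counts over the group, and ratios of few counts had exact 95% intervals. These intervals and floors cover counting error only. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples.

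The gene lists, comparisons, tests, first alternatives and the rule for named genes were fixed before the data were examined. The 26 lists were collagen chains, collagen processing and crosslinking, other extracellular matrix, contractile and myofibroblast genes, TGFβ-responsive genes, matrix proteases and inhibitors, NF-κB targets and feedback, LIGHT receptors and non-canonical NF-κB, lymphoid stroma, chemokines and cytokines, interferon-stimulated genes, MHC class I presentation, IL-13 and STAT6 responsive genes, IL-17 responsive genes, proliferation, glycolysis, the unfolded protein response, cholesterol synthesis, complement, growth factors, fibroblast identity, and markers of epithelial, endothelial, leukocyte, pericyte and smooth muscle, and mesothelial cells. Some genes were in more than 1 list. Lists with at least 5 tested members were tested by camera of limma 3.58.1 on log2 CPM (prior count 2), with the correlation between genes estimated and p-values adjusted over the lists of a comparison. Where a list p is given without another word, it is this adjusted p with an estimated correlation.

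The rule for named genes had 3 parts. Focus genes were given whatever their result: COL1A1, COL1A2, COL3A1, COL5A1, FN1, POSTN, LOX, ACTA2, LTBR, NFKB2, RELB, ICAM1, VCAM1, IL6, CXCL8 and MMP1. The 5 largest rises and 5 largest falls were taken among genes past the threshold with at least 5 CPM in the higher group and no overlap between libraries (for interactions, 5 CPM in any group). Of each list, up to 4 members with the largest changes past the threshold were taken, or the 2 with the highest CPM where none passed. A gene named in 1 comparison could be named in another. XIST and Y-linked genes were left out.

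The alternatives were the size factors of DESeq2 (RLE), no filter beyond 1 read, the Wald test of DESeq2 1.42.0, the replicate number as a block, only the groups compared in the fit, each library left out in turn, and for lists a preset correlation of 0.01. The LIGHT effect after IL-17A against that after IL-13, the LIGHT effect after each cytokine in batch 2 against that of batch 1, the IL-13 effect between batches, and PBS 96 h against PBS 24 h were added after the results had been seen. Group labels were also exchanged among the libraries compared, over all 10 splits of 3 against 3 or up to 100 for interactions. The chain was tested on simulated counts, drawn from a single mean per gene with the depths and estimated dispersions of the real libraries. In them 200 genes were changed, and a list of 20 more was raised by 1.5-fold. Such counts follow the model of the test and hold no deviating library. Fewer genes changed in them than LIGHT changed in the real data, so the shares below may not carry over. For LIGHT against PBS at 24 h, edgeR recovered 59.7%, 74.6% and 93.9% of genes changed by 1.5-, 2- and 4-fold, and 6.25% of its calls were false. For LIGHT after PBS these values were 65.7%, 89.6% and 97.0%, with 4.71% false. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.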

Results

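Transcripts of serum-starved human pulmonary fibroblasts were counted after LIGHT, a cytokine that binds the lymphotoxin beta receptor LTBR, was given alone or with a second cytokine. Batch 1 held 6 analysable groups: PBS, LIGHT, IL-13, LIGHT with IL-13, IL-17A, and LIGHT with IL-17A, all for 24 h. Batch 2 held PBS for 96 h, IL-13 for 72 h, IL-17A for 72 h, and PBS, IL-13 or IL-17A for 72 h followed by LIGHT for 24 h. Each group had n = 3 libraries except IL-17A at 24 h with n = 2. Total counts per library were 26541622 to 36955280 in batch 1 and 19308634 to 32719430 in batch 2. The mitochondrial share was 3.05% to 4.39% in batch 1 and 1.93% to 2.85% in batch 2. In batch 2 it was 2.53% ± 0.286 after PBS then LIGHT and 2.05% ± 0.101 after PBS alone (SD, n = 3). Fold changes below are on the log2 scale with their standard error, and p-values are adjusted p of edgeR unless another test is named.

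The first question was what LIGHT alone changed within 24 h. IL34, a ligand of the macrophage growth factor receptor, rose by 5.43 ± 0.29, from 0.454 ± 0.0557 to 19.7 ± 0.819 CPM (SD, n = 3). BIRC3, an inhibitor of apoptosis induced by NF-κB, rose by 4.85 ± 0.29, from 0.609 ± 0.309 to 17.6 ± 2.07 CPM. TAC3, a tachykinin precursor, rose by 5.06 ± 0.28, and IL4I1, an amino acid oxidase, by 3.74 ± 0.18. NFKB2 and RELB, the subunits of the non-canonical NF-κB dimer, rose by 1.87 ± 0.06 and 1.96 ± 0.07, NFKB2 from 28.1 ± 0.625 to 103 ± 4.90 CPM. The adhesion molecules ICAM1 and VCAM1 rose by 1.71 ± 0.10 and 1.43 ± 0.08. Genes that fell included OGN, a small leucine-rich proteoglycan (fell by 1.54 ± 0.25), OLFML2B (fell by 1.47 ± 0.19), FRZB, a secreted WNT antagonist (fell by 1.32 ± 0.12), MAP2K6 (fell by 1.24 ± 0.12) and TOX3 (fell by 1.17 ± 0.16). MMP9, a gelatinase with 0 reads in the PBS libraries, was at least 13.1-fold higher. In all, 3699 of 17588 genes passed, of which 2328 rose and 1371 fell, and 258 of the rises and 105 of the falls exceeded 1 on the log2 scale.

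On GRCh38, IL34 lies on chromosome 16 from 70579895 to 70660682, BIRC3 on chromosome 11 from 102317450 to 102339403, and TAC3 on chromosome 12 from 57010000 to 57028883. NFKB2 lies on chromosome 10 from 102394110 to 102402529, RELB on chromosome 19 from 45001430 to 45038198, and ICAM1 on chromosome 19 from 10270835 to 10286615. COL1A1 lies on chromosome 17 from 50183289 to 50201632 and COL3A1 on chromosome 2 from 188974320 to 189012746.

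Inflammatory groups rose with LIGHT. Of 21 NF-κB targets 19 rose and 0 fell, and 21 rose when adjusted over the list alone (list adjusted p = 0.000397). The inhibitors NFKBIE and NFKBIA rose by 2.25 ± 0.09 and 2.16 ± 0.06, and TNFAIP3, a deubiquitinase of the same pathway, by 2.02 ± 0.12. Of 11 genes for LIGHT receptors and non-canonical NF-κB 8 rose and 0 fell, with 9 rising when adjusted over the list alone (adjusted p = 0.000275), while LTBR itself was 150 ± 4.23 CPM with PBS and 158 ± 1.30 with LIGHT (adjusted p = 0.235). Of 20 chemokines and cytokines 13 rose and 0 fell, 14 rising when adjusted over the list alone (adjusted p = 0.00263). They included IL32 (3.55 ± 0.17), IL33 (2.73 ± 0.24) and CX3CL1 (2.58 ± 0.33), and the focus genes CXCL8 (0.89 ± 0.23, adjusted p = 0.00749, a call that ended at 0.73 without LIGHT replicate 2) and IL6 (0.95 ± 0.53, adjusted p = 0.225, not passing). Of 15 genes of MHC class I presentation 11 rose and 0 fell, 12 rising when adjusted over the list alone (adjusted p = 0.000275), among them the peptide transporter TAP1 (16.1 ± 0.821 to 34.6 ± 2.54 CPM) and HLA-B (0.80 ± 0.04). Of 18 IL-17 responsive genes 10 rose and 2 fell, 11 and 2 when adjusted over the list alone (adjusted p = 0.0469, 0.05 with a replicate block). Of 14 IL-13 and STAT6 responsive genes 8 rose and 1 fell, 8 and 2 when adjusted over the list alone (adjusted p = 0.0529). Proliferation genes rose in 25 of 28 cases with 0 falls, 27 when adjusted over the list alone, as with TOP2A (1.19 ± 0.22), but adjusted p was 0.158 with an estimated correlation and 1.59e-13 with the preset one.

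Matrix genes went both ways. COL1A1 stood at 10420 ± 1293 CPM with PBS and 10770 ± 438.5 with LIGHT (0.05 ± 0.10, adjusted p = 0.80), and COL1A2 differed by −0.08 ± 0.07 (adjusted p = 0.509). COL3A1 fell by 0.33 ± 0.08, from 3773 ± 161.9 to 2996 ± 200.7 CPM, while COL6A1 rose by 0.58 ± 0.08 and COL6A2 by 0.53 ± 0.08. COL5A1 (−0.12 ± 0.07) and FN1 (0.04 ± 0.07) did not pass. POSTN, a matricellular protein, rose by 0.56 ± 0.06, the crosslinking enzyme LOX by 0.26 ± 0.06, the smooth muscle actin ACTA2 by 0.20 ± 0.07 and the collagenase MMP1 by 0.44 ± 0.09. The ACTA2 call ended without any 1 of the 6 libraries (0.16 to 0.23). Of 21 collagen chains 5 rose and 6 fell, 5 and 6 when adjusted over the list alone (adjusted p = 0.868). Other extracellular matrix genes rose in 5 and fell in 10 of 27 cases, 6 and 11 when adjusted over the list alone (adjusted p = 0.802). Collagen processing and crosslinking genes rose in 8 and fell in 1 of 27 (adjusted p = 0.561), contractile genes rose in 5 and fell in 0 of 18 (adjusted p = 0.802), and TGFβ-responsive genes rose in 6 and fell in 3 of 18 (adjusted p = 0.568), with the same counts when adjusted over the list alone.

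The remaining lists had no call with an estimated correlation. Matrix proteases and inhibitors rose in 8 and fell in 4 of 20 cases (adjusted p = 0.393), lymphoid stroma genes rose in 3 of 11 (adjusted p = 0.158), and interferon-stimulated genes rose in 8 and fell in 2 of 26 (adjusted p = 0.24). IFIT1, an interferon-induced RNA-binding protein, fell by 1.06 ± 0.13 while the RNA sensor IFIH1 rose by 1.30 ± 0.17. Glycolysis genes rose in 10 and fell in 1 of 17 (adjusted p = 0.191), unfolded protein response genes rose in 9 and fell in 1 of 17 (adjusted p = 0.091), and cholesterol synthesis genes rose in 2 of 19 (adjusted p = 0.802). Complement genes rose in 5 and fell in 2 of 12 (adjusted p = 0.0943), led by C3 (2.72 ± 0.15). Growth factors rose in 9 and fell in 4 of 25 (adjusted p = 0.513), among them HBEGF (1.64 ± 0.20) and TGFB2, which fell by 1.16 ± 0.13. Fibroblast identity genes rose in 2 and fell in 5 of 12 (adjusted p = 0.546, median −0.10 but mean 0.07), including TCF21, which fell by 0.45 ± 0.08. Adjusted over the list alone, rises and falls were 8 and 4 for proteases, 4 and 0 for lymphoid stroma, 8 and 2 for interferon-stimulated genes, 11 and 1 for glycolysis, 9 and 2 for the unfolded protein response, 2 and 0 for cholesterol synthesis, 6 and 2 for complement, 11 and 4 for growth factors, and 4 and 6 for fibroblast identity. Markers of other cell types were low or mixed. Endothelial markers rose in 1 and fell in 1 of 7 (adjusted p = 0.877), and pericyte and smooth muscle markers rose in 1 and fell in 2 of 8 (adjusted p = 0.802). Of 4 epithelial markers 1 rose and 1 fell, and neither the 1 leukocyte marker tested, CSF1R (0.411 ± 0.161 and 0.192 ± 0.113 CPM), nor the 1 mesothelial marker, CALB2 (0.4541 ± 0.05835 and 0.651 ± 0.311 CPM), passed. These 3 lists had too few members for a list test.

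**Figure D1:**
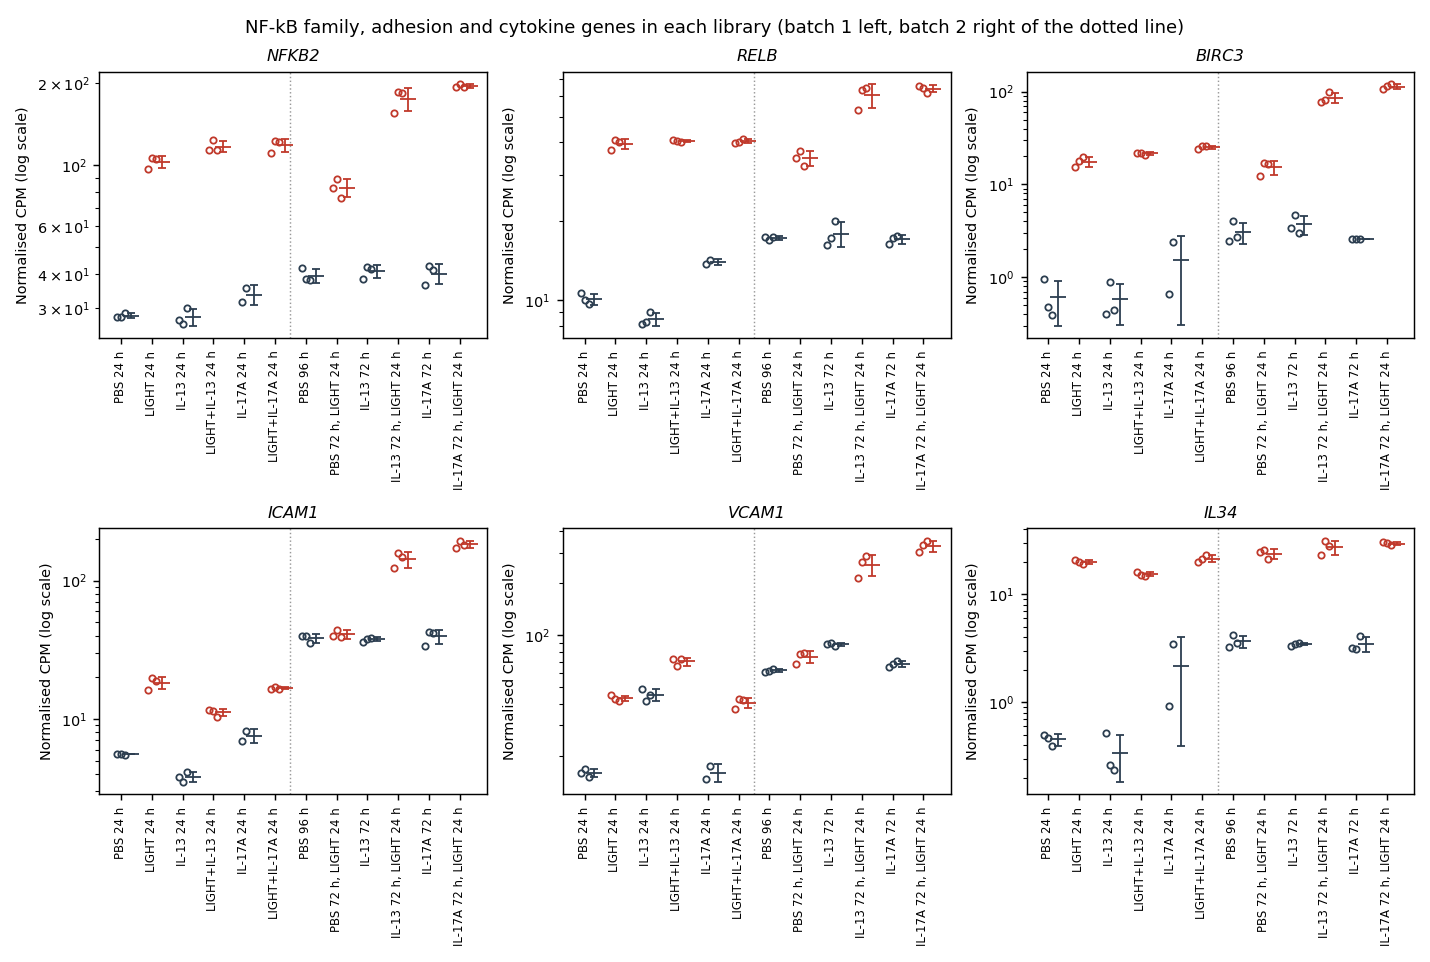
Expression of 6 genes raised by LIGHT (CPM, log axis) in each library of batch 1 and batch 2, by treatment group, with points for libraries and bars for mean and SD. NFKB2 rose from 28.1 to 103 CPM with LIGHT at 24 h in batch 1 and from 39.4 to 82.6 CPM after PBS in batch 2.

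IL-13 for 24 h addressed the response to a type 2 cytokine. CCL26, an eosinophil chemoattractant, had 1310 reads against 2 with PBS, a ratio of 595.9 with an interval of 164.6 to 4925. HS3ST1, a heparan sulfate sulfotransferase, rose by 3.71 ± 0.23 (0.632 ± 0.213 to 8.30 ± 0.806 CPM, SD, n = 3), CAMK2B by 3.44 ± 0.19, and CISH, a feedback inhibitor of STAT signalling, by 2.68 ± 0.09. TSLP, an epithelial-type alarmin, fell by 2.04 ± 0.13, and FMO2, SNCAIP and TFPI2 fell by 1.73 ± 0.11, 1.67 ± 0.12 and 1.52 ± 0.07. VCAM1 rose by 1.51 ± 0.08 and POSTN by 0.81 ± 0.06, whereas ICAM1 fell by 0.54 ± 0.11. The immediate early genes FOS and FOSB also passed (4.07 ± 0.92 and 4.43 ± 1.24), but 1 library, replicate 1 of the IL-13 group, set these values, which were 1.84 ± 0.13 and 0.94 ± 0.22 without it. Their calls also ended without PBS replicate 1 or 2, and that of FOSB without PBS replicate 3. In all 2214 genes passed (1375 rose, 839 fell), and 4207 (2398 and 1809) without that replicate.

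Of 14 IL-13 and STAT6 responsive genes 9 rose and 1 fell with IL-13, 9 and 2 when adjusted over the list alone (adjusted p = 0.0147), the only list past the threshold with an estimated correlation. All 19 cholesterol synthesis genes rose, also when adjusted over the list alone, such as INSIG1 (0.82 ± 0.08), with an adjusted p of 0.158 with an estimated correlation and 1.93e-17 with the preset one. Proliferation genes rose in 20 of 28 cases, 25 when adjusted over the list alone (adjusted p = 0.241 with an estimated correlation), among them UBE2C (1.37 ± 0.20) and TOP2A (1.20 ± 0.22). Glycolysis genes rose in 9 of 17 cases, 13 when adjusted over the list alone (adjusted p = 0.0899), led by hexokinase HK1 (1.14 ± 0.04). Collagen chains rose in 5 and fell in 4 of 21 cases, 8 and 7 when adjusted over the list alone (adjusted p = 0.969). COL7A1 rose by 0.98 ± 0.21 (0.59 ± 0.09 without IL-13 replicate 1) and COL6A1 by 0.68 ± 0.08, while COL15A1 fell by 0.80 ± 0.07. COL1A1 (0.08 ± 0.10), COL1A2 (−0.09 ± 0.07), COL3A1 (−0.24 ± 0.08), COL5A1 (0.12 ± 0.07), FN1 (−0.12 ± 0.07), ACTA2 (0.01 ± 0.07) and MMP1 (0.00 ± 0.09) did not pass. Without IL-13 replicate 1 the falls of COL3A1 (−0.38 ± 0.06), FN1 (−0.21 ± 0.05) and COL1A2 (−0.19 ± 0.05) did pass. COL5A1 ran from −0.01 to 0.21 over 6 fits without 1 library. It passed only at 0.21, without IL-13 replicate 2, which gives more weight to replicate 1. LOX rose by 0.30 ± 0.06.

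IL-17A for 24 h was measured in 2 libraries against 3 with PBS. The neutrophil chemokine CXCL1 rose by 3.05 ± 0.16 (1.604 ± 0.166 to 13.35 ± 2.915 CPM) and CXCL8 by 1.98 ± 0.23, C3 by 2.85 ± 0.16, NFKBIZ, an inducible co-regulator of NF-κB, by 2.24 ± 0.15, and the ribonuclease ZC3H12A by 2.16 ± 0.11. PDK4, a kinase that inhibits pyruvate dehydrogenase, fell by 0.97 ± 0.13, TXNIP by 0.82 ± 0.06, TMEM100 by 0.79 ± 0.18, WNT2B by 0.78 ± 0.19 and ANGPTL4 by 0.74 ± 0.09. The calls of TMEM100 and WNT2B each ended in 4 of 5 fits without 1 library, WNT2B at −0.48 without IL-17A replicate 2. Of 18 IL-17 responsive genes 8 rose and 0 fell, 12 rising when adjusted over the list alone (adjusted p = 0.000527). Chemokines and cytokines rose in 6 of 20 cases, 12 when adjusted over the list alone (adjusted p = 0.00431), NF-κB targets in 7 of 21, 11 when adjusted over the list alone (adjusted p = 0.011), and genes of LIGHT receptors and non-canonical NF-κB in 2 of 11, 5 when adjusted over the list alone (adjusted p = 0.0475, but 0.0645 with RLE size factors and 0.0677 with a replicate block). Contractile genes rose in 7 of 18 cases, 14 when adjusted over the list alone (adjusted p = 0.0957). LOX rose by 0.43 ± 0.07 and the matricellular TNC by 0.52 ± 0.08, while of 21 collagen chains only COL4A1 rose (0.34 ± 0.07, a call that ended in 3 of 5 fits without 1 library), 1 also when adjusted over the list alone (adjusted p = 0.704). COL1A1, COL1A2, COL3A1, COL5A1 and FN1 did not pass (0.11 ± 0.12, 0.04 ± 0.08, −0.14 ± 0.09, 0.16 ± 0.08 and 0.13 ± 0.07). In all 436 genes passed (336 rose, 100 fell). The count was 109 without IL-17A replicate 2, 85 without IL-17A replicate 3, 148 without PBS replicate 1, 184 without PBS replicate 2, 782 by DESeq2 and 761 without the count filter. The 2 IL-17A libraries also differed in genes that LIGHT raised, with 0.666 and 2.40 CPM of BIRC3 and 0.92 and 3.45 CPM of IL34 in replicates 2 and 3.

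LIGHT given together with IL-13 was compared with IL-13 alone to ask whether its effect held in a type 2 setting. TAC3 rose by 6.04 ± 0.30, IL34 by 5.48 ± 0.31 (0.34 ± 0.158 to 15.4 ± 0.659 CPM, SD, n = 3), BIRC3 by 5.23 ± 0.29, IL32 by 4.25 ± 0.16 and IL4I1 from 0.772 ± 0.314 to 12.39 ± 0.899 CPM. H19, an imprinted noncoding RNA, fell by 1.77 ± 0.19, ALS2CL by 1.72 ± 0.31, IFIT1 by 1.71 ± 0.15 and RASSF2 by 1.66 ± 0.14. FOS passed at −2.41 ± 0.79, which again rested on IL-13 replicate 1, since it was −0.20 ± 0.11 (adjusted p = 0.205) without it, and the call also ended without any 1 library of LIGHT with IL-13. All 21 NF-κB targets rose, as did 8 of 11 genes of LIGHT receptors and non-canonical NF-κB and 12 of 15 MHC class I genes, with 0 falls, the same counts when adjusted over the list alone and an adjusted p of 0.000623 each. Chemokines and cytokines rose in 12 and fell in 1 of 20 cases, 13 and 1 when adjusted over the list alone (adjusted p = 0.00427). Of 21 collagen chains 1 rose and 13 fell, 2 and 14 when adjusted over the list alone, but adjusted p was 0.389 with an estimated correlation (2.94e-05 with the preset one). COL3A1 fell by 0.67 ± 0.08, COL5A1 by 0.44 ± 0.07, COL1A1 by 0.35 ± 0.10 (11050 ± 2208 to 8695 ± 425.4 CPM, but −0.19 ± 0.09 and adjusted p = 0.156 without IL-13 replicate 1) and COL1A2 by 0.35 ± 0.07. The COL1A1 call ended in 3 of 6 fits without 1 library, also without replicates 1 and 3 of LIGHT with IL-13 (−0.33 and −0.32). Other extracellular matrix genes rose in 4 and fell in 17 of 27 cases, the same when adjusted over the list alone (adjusted p = 0.189), and FN1 fell by 0.18 ± 0.07 (−0.11 ± 0.05, adjusted p = 0.0816, without IL-13 replicate 1), a call that ended in 4 of 6 fits, also without any 1 library of LIGHT with IL-13. LOX (0.33 ± 0.06), POSTN (0.38 ± 0.06), VCAM1 (0.64 ± 0.07), ICAM1 (1.54 ± 0.10) and MMP1 (0.25 ± 0.09, a call that ended in 5 of 6 fits without 1 library) rose. All 28 proliferation genes rose, also when adjusted over the list alone (adjusted p = 0.142). In all 5273 genes passed (2828 rose, 2445 fell), and 4637 without IL-13 replicate 1.

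The interaction of LIGHT and IL-13 at 24 h tested whether LIGHT acted differently in the presence of IL-13. VCAM1 had 15.9 ± 0.914 CPM with PBS, 42.9 ± 1.59 with LIGHT, 45.1 ± 3.68 with IL-13 and 70.4 ± 3.75 with both. Its fold change with LIGHT was thus smaller over IL-13 (interaction −0.79 ± 0.10, adjusted p = 0.000123). The interaction is on the log2 scale, and in CPM the rise was similar in both backgrounds. HS3ST1 (1.95 ± 0.44), TIPIN (0.92 ± 0.20), SPINT2 (0.91 ± 0.17), RGS4 (0.84 ± 0.18) and ANK2 (0.80 ± 0.10) had a higher signed LIGHT effect over IL-13. For HS3ST1 the sign turned, from 0.632 to 0.229 CPM with LIGHT over PBS (57 and 20 reads) and from 8.30 to 11.8 CPM over IL-13. FMO2 (−1.49 ± 0.17), ACPP (−0.98 ± 0.22), MN1 (−0.93 ± 0.20), IL16 (−0.82 ± 0.18) and A2M (−0.81 ± 0.15) had a lower one. Of 21 collagen chains 0 were higher and 3 lower, COL14A1 (−0.46 ± 0.10), COL4A1 (−0.45 ± 0.09) and COL4A2 (−0.41 ± 0.09), and 13 were lower when adjusted over the list alone (adjusted p = 0.181). For COL1A1 the interaction was −0.39 ± 0.15 (adjusted p = 0.418) and for COL3A1 −0.34 ± 0.12 (adjusted p = 0.35). Over 12 fits without 1 library they ran from −0.52 to −0.23 and from −0.45 to −0.2. Only the lowest values passed, without IL-13 replicate 2. That fit gives more weight to IL-13 replicate 1, where COL1A1 was 13370 CPM against 8852 and 10820 in replicates 2 and 3. The calls of VCAM1, SPINT2, ANK2 and FMO2 held in each of 12 fits without 1 library, while those of HS3ST1, TIPIN, RGS4, ACPP, MN1, IL16, A2M, COL14A1, COL4A1 and COL4A2 ended in 6 to 9 of the 12 with their direction kept. In all 92 genes passed, 22 higher and 70 lower. The count moved with the libraries, to 214 without IL-13 replicate 1, 226 without IL-13 replicate 2, 39 without PBS replicate 1, 39 without PBS replicate 2, 54, 47 and 38 without LIGHT replicates 1, 2 and 3, and 39 and 40 without replicates 2 and 3 of LIGHT with IL-13.

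LIGHT with IL-17A was compared with IL-17A alone. BIRC3 rose by 4.09 ± 0.29 (1.53 ± 1.23 to 25.1 ± 1.04 CPM), TAC3 by 3.69 ± 0.27, IL34 by 3.33 ± 0.27, the neutrophil chemokine CXCL6 by 3.24 ± 0.29 and IL32 by 3.16 ± 0.18. The 2 IL-17A libraries differed in BIRC3 and IL34, as given above, so the sizes of these 2 rises depend on which library is used. CXCL1 rose by 2.44 ± 0.12, from 13.35 ± 2.915 to 72.3 ± 3.31 CPM, and CXCL8 by 1.68 ± 0.19. H19 fell by 1.71 ± 0.20, IFIT1 by 1.44 ± 0.15, TOX3 by 1.36 ± 0.19, COL21A1 by 1.29 ± 0.13 and the complement component C7 by 1.24 ± 0.15. NF-κB targets rose in 19 of 21 cases, 20 when adjusted over the list alone (adjusted p = 0.00042), chemokines and cytokines in 14 of 20 with 1 fall, 15 and 1 when adjusted over the list alone (adjusted p = 0.00042), MHC class I genes in 11 of 15, 12 when adjusted over the list alone (adjusted p = 0.000294), and IL-17 responsive genes in 10 of 18 with 1 fall, 12 and 2 when adjusted over the list alone (adjusted p = 0.0075). Collagen chains rose in 3 and fell in 7 of 21 cases, 4 and 7 when adjusted over the list alone (adjusted p = 0.658), with COL3A1 falling by 0.42 ± 0.09 (a call that ended at −0.37 without IL-17A replicate 2, 1 of 2 libraries of its group) and COL1A1 at −0.01 ± 0.12 (adjusted p = 0.971). In all 3007 genes passed (1850 rose, 1157 fell), against 1359 and 1909 without IL-17A replicates 2 and 3. In the interaction of LIGHT and IL-17A edgeR called 2 genes, the NF-κB inhibitor NFKBIA (−0.75 ± 0.08) and CST1, a cystatin (−0.87 ± 0.14), both with a smaller LIGHT effect over IL-17A. The NFKBIA call held in each of 11 fits without 1 library, and the CST1 call ended in 4, those without PBS replicates 1 and 3, IL-17A replicate 3 and replicate 1 of LIGHT with IL-17A. There were 712 genes at an unadjusted p under 0.05 and 9 calls by DESeq2. The count was 1 without PBS replicate 1, IL-17A replicate 3 or replicate 1 of LIGHT with IL-17A, and 5 without IL-17A replicate 2.

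**Figure D2:**
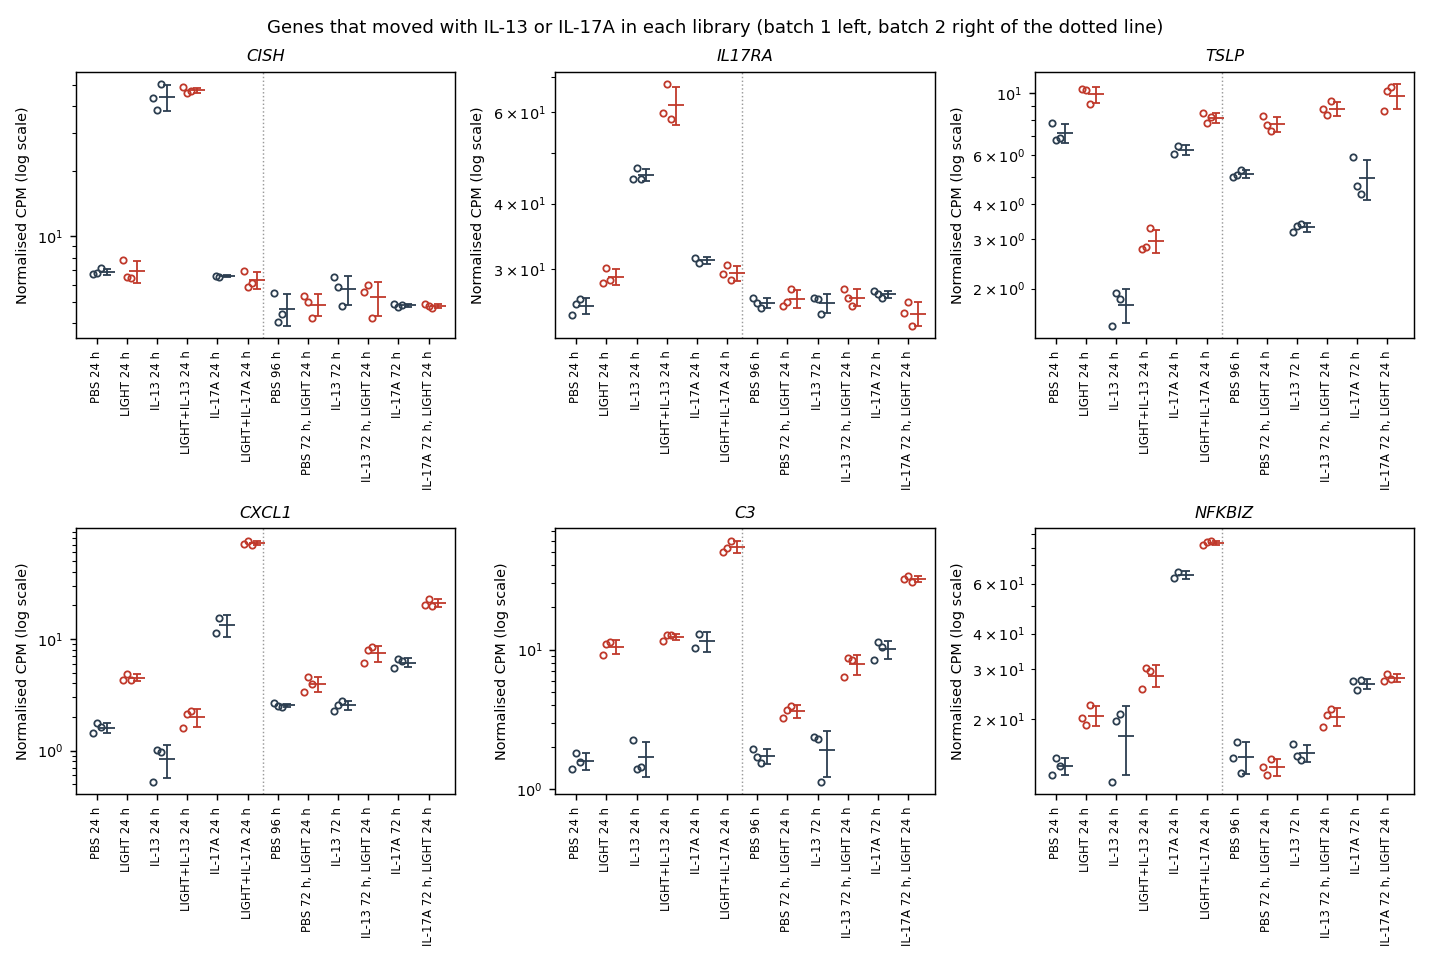
Expression of 6 genes that respond to IL-13 or IL-17A (CPM, log axis) in each library of both batches, by treatment group, with points for libraries and bars for mean and SD. CISH rose from 6.89 to 44.0 CPM with IL-13 at 24 h and was 5.71 CPM with IL-13 and 4.64 CPM with PBS in batch 2.

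In batch 2 LIGHT was added after 72 h of PBS and compared with PBS for 96 h. TAC3 rose by 4.75 ± 0.15 (0.844 ± 0.116 to 22.55 ± 2.905 CPM, SD, n = 3), CST1 by 3.65 ± 0.25, the adhesion molecule L1CAM by 2.76 ± 0.11, IL34 by 2.71 ± 0.11 and BIRC3 by 2.34 ± 0.21. C11orf87 fell by 2.42 ± 0.16, GDF10 and the potassium channel gene KCNJ2 by 2.25 ± 0.22 and 2.25 ± 0.12, ELN, the elastin gene, by 1.90 ± 0.12, and C7 by 1.86 ± 0.16. Several matrix and contractile genes fell, although no list passed with an estimated correlation. COL1A1 fell by 0.44 ± 0.05 (31910 ± 2405 to 23490 ± 1362 CPM), COL5A1 by 0.41 ± 0.05, COL1A2 by 0.40 ± 0.04, COL3A1 by 0.23 ± 0.05, ACTA2 by 0.58 ± 0.04, POSTN by 0.56 ± 0.09 and LOX by 0.41 ± 0.04, while FN1 (−0.06 ± 0.05, adjusted p = 0.359) did not pass and MMP1 rose by 0.82 ± 0.08. Of 29 other extracellular matrix genes 1 rose and 21 fell, the same when adjusted over the list alone, and of 18 contractile genes 1 rose and 12 fell, 1 and 13 when adjusted over the list alone (adjusted p = 0.0782 for each). Collagen chains rose in 7 and fell in 13 of 21 cases, 8 and 13 when adjusted over the list alone (adjusted p = 0.553), COL6A1 rising by 0.50 ± 0.04.

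NFKB2 and RELB rose by 1.07 ± 0.07 and 1.02 ± 0.07 after PBS, but ICAM1 (38.3 ± 2.76 to 40.9 ± 2.77 CPM, adjusted p = 0.538) and VCAM1 (0.26 ± 0.10, adjusted p = 0.0617) did not pass. VCAM1 passed at 0.32 without replicate 1 of PBS then LIGHT. CXCL8 fell by 0.67 ± 0.16. NF-κB targets rose in 14 of 21 cases, 15 when adjusted over the list alone, chemokines and cytokines rose in 10 and fell in 1 of 20, the same when adjusted over the list alone, and MHC class I genes rose in 11 of 15, 12 when adjusted over the list alone, each with an adjusted p of 0.0782. All 28 proliferation genes rose, also when adjusted over the list alone (adjusted p = 0.089), such as MKI67 (0.76 ± 0.12). Growth factors rose in 6 and fell in 14 of 25 cases, 8 and 15 when adjusted over the list alone (adjusted p = 0.24). Pericyte and smooth muscle markers fell in 4 of 8 cases and rose in 1, the same when adjusted over the list alone (adjusted p = 0.0955), including MYH11 (fell by 1.66 ± 0.11). Of 16521 genes 5417 passed (2656 rose, 2761 fell), and 5376 without replicate 3 of the LIGHT group, whose RN7SL2 level stood apart.

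**Figure D3:**
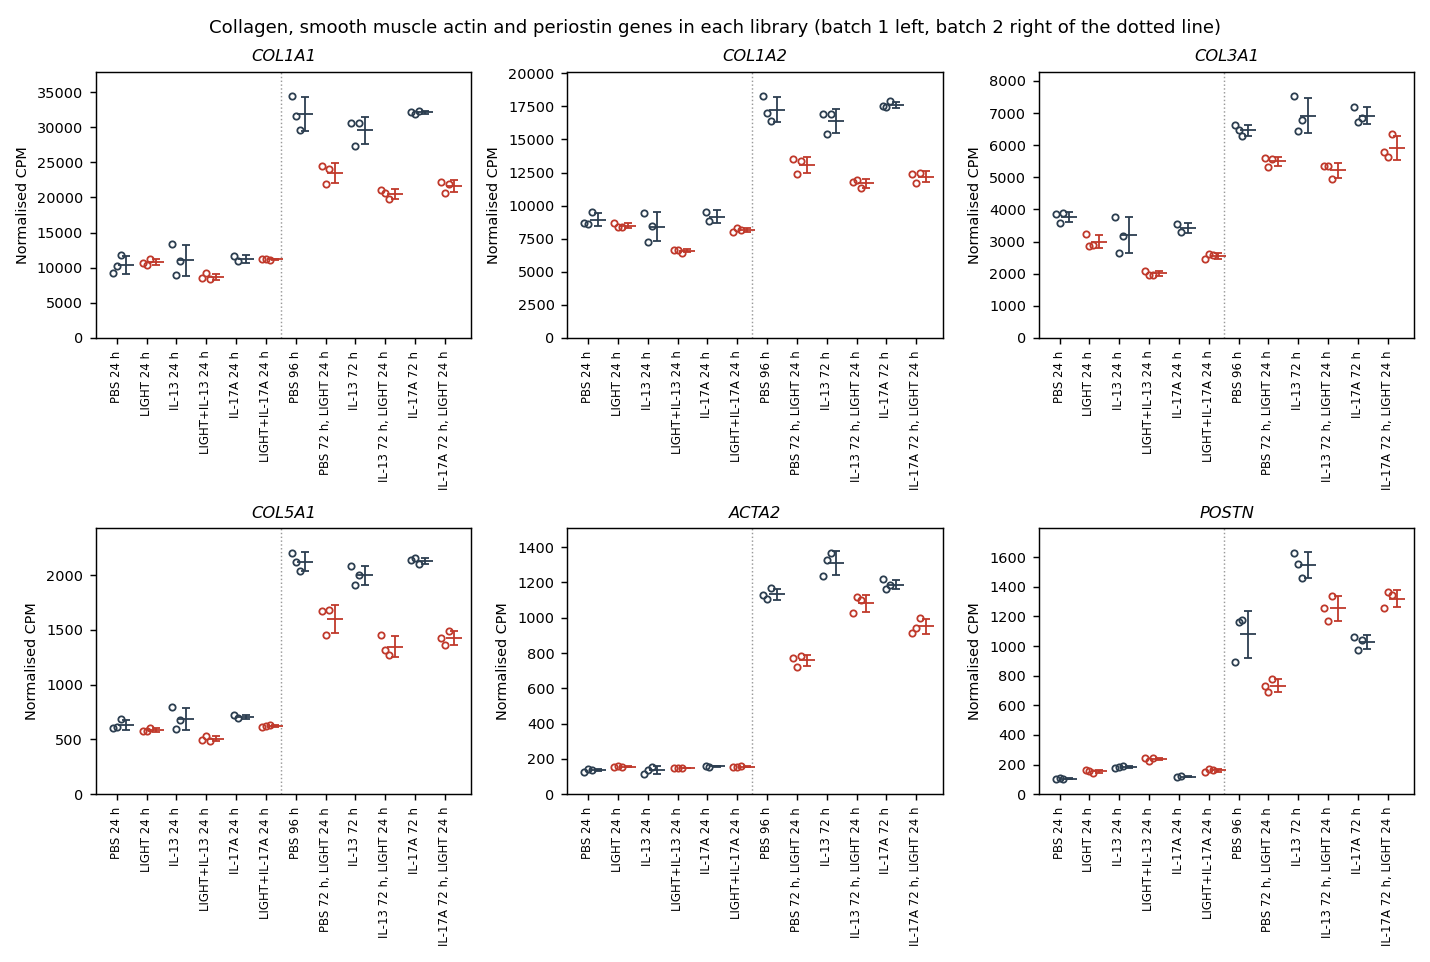
Expression of 4 collagen genes, ACTA2 and POSTN (CPM) in each library of both batches, by treatment group, with points for libraries and bars for mean and SD. COL1A1 had 10420 CPM with PBS and 10770 CPM with LIGHT in batch 1, and 31910 CPM with PBS and 23490 CPM with PBS then LIGHT in batch 2.

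IL-13 and IL-17A for 72 h were compared with PBS for 96 h. The labels do not say whether these cytokine cultures were harvested at 72 or 96 h, so time in culture may have differed. With IL-13, SPTBN5 rose by 0.93 ± 0.10, GDF6, a ligand of the BMP family, by 0.90 ± 0.09, and IL6 by 0.86 ± 0.16, and NPTX1 fell from 37.2 ± 2.39 to 17.3 ± 1.80 CPM, HSD11B1, a glucocorticoid-activating enzyme, by 0.97 ± 0.12 and MMP1 by 0.84 ± 0.09. POSTN rose by 0.52 ± 0.09, VCAM1 by 0.50 ± 0.10 and ACTA2 by 0.21 ± 0.04, FN1 fell by 0.30 ± 0.05, and TSLP fell by 0.63 ± 0.12. CISH was 4.64 ± 0.767 and 5.71 ± 0.875 CPM (adjusted p = 0.185), and COL1A1 did not pass (−0.11 ± 0.05, passing at −0.16 without PBS replicate 3). IL-13 and STAT6 responsive genes rose in 5 and fell in 2 of 12 cases, 7 and 2 when adjusted over the list alone (adjusted p = 0.338), and contractile genes rose in 5 and fell in 1 of 18, 8 and 1 when adjusted over the list alone (adjusted p = 0.306). With IL-17A, C3 rose by 2.54 ± 0.17, CXCL1 by 1.27 ± 0.13, IL6 by 0.89 ± 0.16, NFKBIZ by 0.86 ± 0.07 and CXCL8 by 0.52 ± 0.14 (ended in 4 of 6 fits without 1 library), and IL-17 responsive genes rose in 7 of 18 cases, also when adjusted over the list alone (adjusted p = 0.0423, but 0.0975 with a replicate block). With IL-17A, GRIA4 fell by 0.62 ± 0.11 and HTR2B by 0.59 ± 0.10, and COL1A1 was at 0.01 ± 0.05 (adjusted p = 0.919). With IL-13 1001 genes passed (564 rose, 437 fell), and 444, 570 and 653 without PBS replicate 1, IL-13 replicate 2 and IL-13 replicate 3, while without PBS replicate 3 fewer rose than fell (364 and 381). With IL-17A 1783 passed (773 rose, 1010 fell), with 811 and 987 without PBS replicates 2 and 3 and 966, 942 and 1104 without IL-17A replicates 1, 2 and 3. The balance of directions moved too, to 416 rising and 1228 falling without the filter on low counts, 333 and 654 without PBS replicate 3 and 341 and 625 without IL-17A replicate 1. In the main fit 10 rises and 11 falls with IL-13, and 8 rises and 9 falls with IL-17A, exceeded 1 on the log2 scale.

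LIGHT after 72 h of IL-13 or IL-17A was compared with the cytokine alone for 72 h, a control that may have had 24 h less in culture. After IL-13, TAC3 rose by 5.23 ± 0.16, BIRC3 by 4.53 ± 0.17 (3.70 ± 0.864 to 86.0 ± 11.5 CPM, SD, n = 3), CST1 by 3.97 ± 0.26, MOB3B by 3.80 ± 0.15 and SLCO2A1, a prostaglandin transporter, by 3.78 ± 0.13. After IL-17A, BIRC3 rose by 5.45 ± 0.18 (2.58 ± 0.03 to 113 ± 7.25 CPM), TAC3 by 5.33 ± 0.15 and MOB3B by 4.16 ± 0.14, and MMP9, with 0 reads after IL-17A alone, was at least 38.4-fold higher. ICAM1 rose by 1.92 ± 0.10 and 2.21 ± 0.10, VCAM1 by 1.53 ± 0.09 and 2.27 ± 0.09, and NFKB2 by 2.09 ± 0.07 and 2.28 ± 0.07 after IL-13 and IL-17A. The fibroblast transcription factor TCF21 fell by 1.81 ± 0.12 and 2.03 ± 0.12, and BMP6, a growth factor, by 2.29 ± 0.15 and 2.78 ± 0.16. COL1A1 fell by 0.53 ± 0.05 and 0.57 ± 0.05, COL1A2 by 0.49 ± 0.04 and 0.53 ± 0.04, COL5A1 by 0.57 ± 0.05 and 0.58 ± 0.05, and COL3A1 by 0.41 ± 0.05 and 0.22 ± 0.05. ACTA2 fell by 0.28 ± 0.04 and 0.32 ± 0.04, and ELN by 1.00 ± 0.11 and 1.18 ± 0.12. POSTN fell by 0.30 ± 0.09 after IL-13 (ended in 2 of 6 fits without 1 library) and rose by 0.36 ± 0.09 after IL-17A, and LOX was at −0.03 ± 0.04 (adjusted p = 0.559) after IL-13 and rose by 0.30 ± 0.04 after IL-17A. LTBR was at −0.05 ± 0.04 (adjusted p = 0.374) after IL-13 and fell by 0.15 ± 0.04 after IL-17A.

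After IL-13, NF-κB targets rose in 20 of 21 cases and chemokines and cytokines in 17 of 20 with 1 fall, 20 and 18 rising when adjusted over the list alone (adjusted p = 0.0273 for each). After IL-17A the same lists rose in 19 of 21 and 18 of 20 cases, also when adjusted over the list alone (adjusted p = 0.0487 for each). With RLE size factors adjusted p was 0.0505 for each, so these calls were lost. With a replicate block it was 0.0552 for NF-κB targets. MHC class I genes rose in 15 of 15 and 12 of 15 cases, also when adjusted over the list alone (adjusted p = 0.05 and 0.182, neither past the threshold). Contractile genes fell in 16 of 18 with 0 rises after IL-13, 16 and 1 when adjusted over the list alone (adjusted p = 0.124), and fell in 12 and rose in 2 after IL-17A, also when adjusted over the list alone (adjusted p = 0.212). Collagen chains rose in 7 and fell in 13 of 21 after IL-13, also when adjusted over the list alone (adjusted p = 0.603), and rose in 7 and fell in 10 after IL-17A, 7 and 11 when adjusted over the list alone (adjusted p = 0.719). Other extracellular matrix genes fell in 21 of 29 and in 23 of 29 cases, 22 and 23 when adjusted over the list alone (adjusted p = 0.155 and 0.228). In all 8551 genes passed after IL-13 (4230 rose, 4321 fell) and 9681 after IL-17A (4825 rose, 4856 fell).

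**Figure D4:**
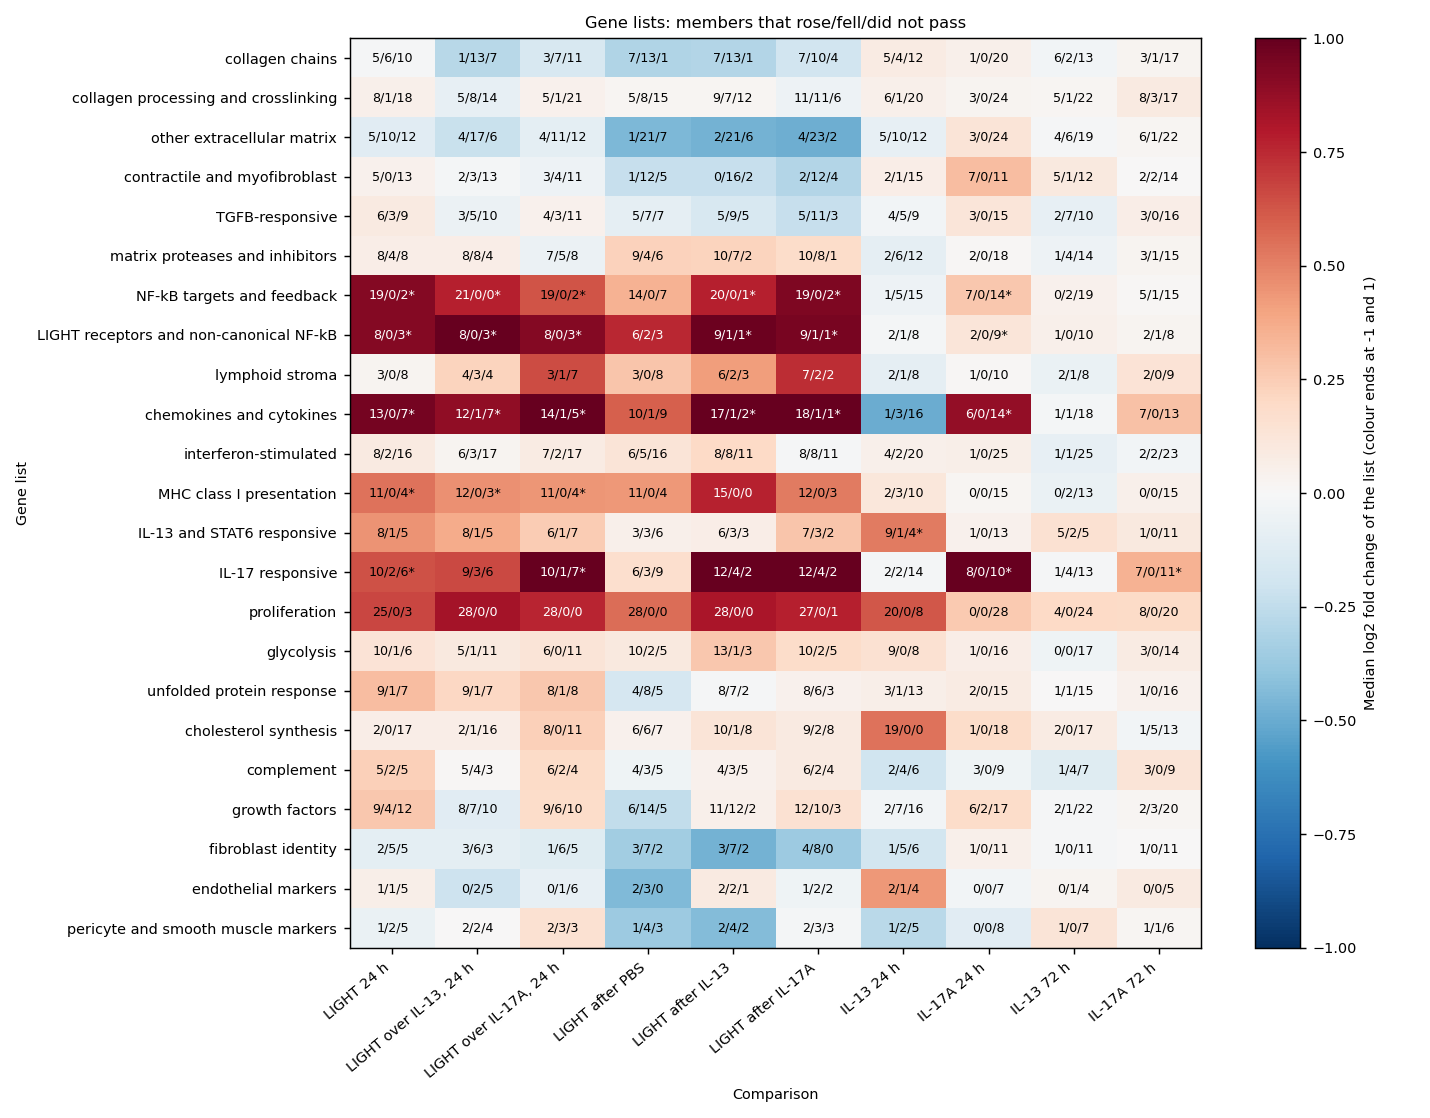
Median log2 fold change of the tested members of each gene list (colour) for LIGHT in each background and for IL-13 and IL-17A alone, with members that rose, fell and did not pass printed in each cell and a star where the list test passed. NF-κB targets have a median of 0.92 for LIGHT at 24 h, 0.35 after PBS, 0.78 after IL-13 and 0.93 after IL-17A.

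Interactions tested whether the LIGHT effect after a cytokine differed from that after PBS within batch 2. The PBS control was labelled 96 h and the cytokine controls 72 h, so these interactions may hold a difference in time in culture. ICAM1 had 38.3 ± 2.76 CPM with PBS, 40.9 ± 2.77 with PBS then LIGHT, 143 ± 18.6 with IL-13 then LIGHT and 183 ± 10.9 with IL-17A then LIGHT, with interactions of 1.82 ± 0.15 and 2.11 ± 0.15. VCAM1 differed by 1.28 ± 0.13 and 2.01 ± 0.13, CXCL8 by 1.41 ± 0.21 and 1.89 ± 0.20, BIRC3 by 2.19 ± 0.31 and 3.11 ± 0.33, TRAF1 by 2.09 ± 0.22 and 2.29 ± 0.22, and NFKB2 by 1.02 ± 0.10 and 1.21 ± 0.10 after IL-13 and IL-17A. IL6 differed by 0.65 ± 0.24 (ended in 7 of 12 fits without 1 library) and 1.33 ± 0.23, LOX by 0.38 ± 0.06 and 0.71 ± 0.06, and ACTA2 by 0.30 ± 0.06 and 0.26 ± 0.06, while POSTN passed after IL-17A (0.92 ± 0.13) and not after IL-13 (0.26 ± 0.13, adjusted p = 0.193, but passing at 0.37 without PBS replicate 1). PPL, a desmosomal linker protein, had interactions of −1.68 ± 0.08 and −2.00 ± 0.08. For COL1A1 they were −0.08 ± 0.07 (adjusted p = 0.425) and −0.13 ± 0.07 (adjusted p = 0.128), the second passing in 2 of 12 fits without 1 library. NF-κB targets were higher in 17 of 21 cases after IL-13, 18 when adjusted over the list alone (adjusted p = 0.036), and in 15 of 21 after IL-17A, also when adjusted over the list alone (adjusted p = 0.116). In all 3621 genes passed for IL-13 (1994 higher, 1627 lower) and 6745 for IL-17A (3564 and 3181), or 3487 and 6681 without replicate 3 of PBS then LIGHT. With all libraries, 80 and 201 were higher and 153 and 311 lower by over 1 on the log2 scale for IL-13 and IL-17A.

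The LIGHT effect over PBS was also compared between batch 2, with 96 h in culture, and batch 1, with 24 h. It was smaller in batch 2 for VCAM1 (−1.16 ± 0.12), BIRC3 (−2.50 ± 0.43), IL34 (−2.71 ± 0.36), RELB (−0.93 ± 0.10) and NFKB2 (−0.78 ± 0.10), and lower for COL1A1 (−0.47 ± 0.12), COL1A2 (−0.31 ± 0.08), ACTA2 (−0.76 ± 0.09), TNC (−1.43 ± 0.10) and LOX (−0.66 ± 0.08). MIAT, a noncoding RNA, had a higher effect in batch 2 (1.91 ± 0.24). RN7SL2, the RNA of the signal recognition particle, passed at 6.05, a value set by replicate 3 of PBS then LIGHT, since it was 0.04 ± 0.71 (adjusted p = 0.988) without it. NF-κB targets were lower in 14 of 21 cases and higher in 0, 14 and 1 when adjusted over the list alone (adjusted p = 0.00271), and other extracellular matrix genes were lower in 16 and higher in 1 of 29, 17 and 2 when adjusted over the list alone (adjusted p = 0.0259). Also lower were 8 of 11 genes of LIGHT receptors and non-canonical NF-κB, 9 when adjusted over the list alone (adjusted p = 0.00214), and 5 of 14 IL-13 and STAT6 responsive genes, 5 when adjusted over the list alone with 1 higher (adjusted p = 0.0153). Unfolded protein response genes were lower in 8 of 17 cases and complement genes in 4 of 12, 11 and 5 when adjusted over the list alone (adjusted p = 0.0259 and 0.0278). Collagen chains were lower in 10 and higher in 2 of 21, 10 and 3 when adjusted over the list alone (adjusted p = 0.657). In all 2655 of 18239 genes passed (1026 higher, 1629 lower), and 2615 without replicate 3 of PBS then LIGHT. Batch and time in culture cannot be told apart here.

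LIGHT responses were then compared between pairs of experiments that shared no library. Of the genes that passed at 24 h over PBS and over IL-13, 1833 rose in both, where 374.3 would be shared by independent lists, and 1019 fell in both, where 190.6 would be, and 99.8% of the 2859 genes past both thresholds moved the same way. Over PBS and over IL-17A 1531 rose and 768 fell in both. In batch 2, 97.7% of the 6691 genes past both thresholds after IL-13 and IL-17A moved the same way, and across genes, which are not independent replicates, the fold changes correlated at 0.83. After PBS and after IL-13 95.8% of 4206 genes moved the same way, with a correlation of 0.65 across genes. For PBS and IL-17A it was 80.8% of 4104 genes, with a correlation of 0.56. The control was labelled 72 h for both cytokines and 96 h for PBS. A difference in time in culture may therefore raise the agreement between the cytokine pretreatments and lower that with PBS. At 24 h the correlation was 0.65 between PBS and IL-13 backgrounds and 0.58 between PBS and IL-17A backgrounds. For LIGHT over PBS in the batches 84.9% of 2018 shared genes moved the same way, with a correlation of 0.4. For IL-13 at 24 h and 72 h 202 rose in both (46.91 for independent lists) and 118 fell in both (22.3), and the slope of the 72 h on the 24 h fold changes was 0.14 over genes called at 24 h. For IL-17A 75 rose in both (15.98) and the slope was 0.20.

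LIGHT after 72 h of TGFβ was compared with TGFβ alone on rows without gene names, since these 6 columns did not line up with the row names. Of 15810 rows tested 9405 passed, 4561 higher and 4844 lower in the LIGHT group (n = 3 per group). The largest rise was 9.56 and the largest fall −9.40 on the log2 scale. The control was labelled 72 h and may have had 24 h less in culture, so LIGHT and time in culture may both have contributed. No gene, list or collagen result can be given for these groups.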

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

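The tests of explanations for the 3 patterns below, and the splits of the contrasts between LIGHT effects after IL-13 or IL-17A and at 24 h, between the IL-13 effects of the batches and between the PBS groups, were chosen after the results were seen. The results here are effects that differed between backgrounds, pretreatments or batches by a test of the difference itself.

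At 24 h the LIGHT effect differed with IL-13 in 92 genes and with IL-17A in 2. With IL-13 the differences were −0.79 for VCAM1, 1.95 for HS3ST1, 0.80 for ANK2, 0.91 for SPINT2, −1.49 for FMO2 and −0.93 for MN1, and with IL-17A −0.75 for NFKBIA and −0.87 for CST1. In 10 of 100 splits of the 12 libraries, which exchanged LIGHT and control labels within each background, as many genes passed as the 92 with IL-13. These 10 splits, the real one included, each kept LIGHT libraries and their controls apart in at least 1 background. Such splits hold LIGHT effects, alone or summed over backgrounds, in place of their difference, and the highest other one called 6847 genes. Their number therefore decides nothing about chance for the difference. The 85 splits that mixed LIGHT and control libraries in both backgrounds called at most 0. Mixing puts LIGHT and control libraries in the same group, which widens the spread within groups and can lower the count by itself. These splits therefore decide nothing about chance either.

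In batch 2 the LIGHT effect after IL-13 differed from that after PBS in 3621 genes, and after IL-17A in 6745. Of these, 80 and 201 were higher and 153 and 311 lower by over 1 log2 unit, and the median sizes were 0.35 and 0.41. The common coefficient of variation between replicates was 0.0398 in batch 2 and 0.0618 in batch 1. Counts of called genes in the 2 batches are therefore not directly comparable. After IL-13 the differences were 1.82 for ICAM1, 1.28 for VCAM1, 1.41 for CXCL8, 1.02 for NFKB2, 0.74 for RELB, 2.19 for BIRC3, 2.09 for TRAF1, 2.40 for SLCO2A1 and −1.68 for PPL. After IL-17A they were 2.11 for ICAM1, 2.01 for VCAM1, 1.89 for CXCL8, 1.33 for IL6, 1.21 for NFKB2, 0.89 for RELB, 3.11 for BIRC3, 2.96 for CXCL5, 0.92 for POSTN, 0.71 for LOX and −2.00 for PPL. As many genes passed in 6 and 5 of 100 splits for IL-13 and IL-17A, and the highest other splits called 8972 and 9072 genes. The splits that reached the real counts again kept LIGHT libraries and controls apart after at least 1 pretreatment, so their number decides nothing about chance here either. The 85 that mixed them in both called at most 0, which again decides nothing because mixing widens the spread within groups.

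Between the batches the LIGHT effect over PBS differed in 2655 genes, by −1.6 for ICAM1, −1.16 for VCAM1, −0.78 for NFKB2, −0.93 for RELB, −2.50 for BIRC3, −2.71 for IL34, −0.47 for COL1A1, −0.31 for COL1A2, −0.76 for ACTA2, −1.1 for POSTN, −0.66 for LOX and 1.91 for MIAT. As many genes passed in 3 of 100 splits, with 5619 in the highest other split and at most 0 in the 85 that mixed LIGHT and control libraries in both batches. LIGHT effects after IL-17A and after IL-13 differed in 2686 genes (10 of 100 splits called as many, the highest other 10761). The effect after IL-13 differed from the 24 h effect of batch 1 in 2612 genes (8 of 100, highest other 8235), the effect after IL-17A from it in 4270 (8 of 100, highest other 8992), and the IL-13 effects of the batches from one another in 1172 (6 of 100, highest other 2389, and at most 1014 in the 85 splits that mixed IL-13 and control libraries in both batches). In each of these 5 contrasts the splits that reached the real count kept treated libraries and controls apart in at least 1 arm, so their number decides nothing about chance. Splits that mixed them decide nothing either, because mixing widens the spread within groups. The counts moved to 1710 without replicate 2 of IL-13 then LIGHT for LIGHT after IL-17A against after IL-13, and to 2913 without replicate 1 of IL-13 at 24 h for the IL-13 effects.

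For comparisons of 3 libraries with 3 the 10 splits were too few for a share under 0.05, and the real split, 1 of 10, was the only one to reach the real count in each. The other splits mixed the groups compared, which widens the spread within groups and can lower their counts by itself. Real counts and the highest of the other splits were 3699 and 0 for LIGHT at 24 h, 2214 and 308 for IL-13 at 24 h, 5273 and 0 for LIGHT over IL-13, 5417 and 0 for LIGHT after PBS, 1001 and 1 for IL-13 for 72 h, and 1783 and 0 for IL-17A for 72 h. They were 8551 and 0 for LIGHT after IL-13, 9681 and 0 for LIGHT after IL-17A, 9405 and 0 for LIGHT after TGFβ, and 11220 and 0 for PBS for 96 h against 24 h.

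The LIGHT effect in batch 2 was lower over PBS than over IL-17A in 15 of 21 NF-κB target genes and higher in 0, with a median difference of 0.66 over the 21, but the list did not pass with an estimated correlation (adjusted p = 0.116). Without replicate 3 of PBS then LIGHT the median was 0.62, which argues against that library as the whole explanation (no other library was left out for this median), and the sign-turned difference of the controls was −0.01, which argues against a difference between the controls, from their time in culture or otherwise, unless time in culture cancelled an effect of IL-17A. Against batch 1 the LIGHT effect after IL-17A differed by a median of 0.01 and that after PBS by −0.56. For this list the PBS arm may therefore be the one out of line. Over all genes the picture was mixed. More genes differed from batch 1 after IL-17A (4270) than after PBS (2655), yet the correlation with batch 1 across genes was higher after IL-17A (0.61 against 0.4). Of 240 genes that LIGHT raised by over 1 log2 unit in batch 1, 115 rose more over IL-17A and 120 did not differ. Of the same genes 2.08% rose more over PBS. A weaker LIGHT stimulus over PBS could give such counts. Any other cause of a lower response over PBS could too, so the counts do not decide between them. Raised genes were not alike, since TAC3 still rose strongly after PBS while ICAM1 did not pass. A weaker stimulus alone would not give a larger fall over PBS, as seen for ELN (−1.90 against −1.18). The 2 controls may have differed in time in culture, however, and ELN also differed between the PBS groups of the batches. Nor would it turn a rise into a fall, as with CXCL8 and POSTN, which LIGHT raised at 24 h and lowered after PBS. That contrast is between batches, where batch and time in culture cannot be told apart. These genes therefore do not decide about a weaker stimulus. A cancellation of an IL-17A effect by time in culture and an effect of the pretreatments on the LIGHT response stay open and were not tested.

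The 18 genes that IL-13 raised by over 2 log2 units at 24 h, with a median of 2.86, had a median of 0.39 at 72 h, where 7 of them rose. Yet 320 genes were called in the same direction at both times against 69.17 for independent lists. That argues against libraries without IL-13, unless time in culture moved the same genes. CCL26 gave little sign of IL-13, with 8 reads over 3 libraries of IL-13 for 72 h (0.0934 CPM, against 13.48 CPM at 24 h). It had 0 reads with PBS for 96 h. HS3ST1 was at 0.348 CPM with IL-13 for 72 h and 0.137 CPM with PBS. Libraries without IL-13 are therefore not excluded. Among IL4R, IL13RA1, JAK1 and STAT6 the lowest difference of PBS for 96 h from PBS for 24 h was −0.68, for STAT6, which argues against a loss of over 1 log2 unit of these transcripts as the explanation. A smaller loss and a transient response stay open, and harvest time and batch cannot be told apart here.

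Replicate 1 of IL-13 at 24 h stood apart from the other IL-13 libraries, with 188.9 CPM of FOS against 16.09 and 15.13, although EGR1, also an immediate early gene, was lower (235.6 against 426.2 and 466). Its CCL26 level of 12.1 CPM, against a mean of 14.16 in the others, argues against a library without IL-13. Reads outside protein-coding and mitochondrial genes made up 1.69% of it against at most 1.61% in the 16 other libraries of batch 1. More noncoding RNA is therefore a candidate explanation, on a small margin and not for each such RNA, since RN7SL2 was lower (10.56 against 41.54 and 37.44 CPM). The 1.61% was that of PBS replicate 3, and outside the group with IL-13 alone FOS was at most 14.55 CPM in batch 1. A share almost as high thus came without high FOS, so the share does not decide. No biological explanation was tested.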

How the results depend on the processing

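Alternatives for the contrasts between LIGHT effects after IL-13 or IL-17A and at 24 h, between the IL-13 effects of the batches, between the PBS groups, and for shared calls were chosen after seeing the data. DESeq2 size factors (RLE) and a replicate block left each of 21 counts of called genes within 1.5 times its main value, no filter and the DESeq2 test left 18 of 21 there, and a fit of only the compared groups 13 of 20. Without the filter the counts were 761 for IL-17A at 24 h, 198 for the interaction of LIGHT and IL-13 at 24 h and 14 for that with IL-17A, and by DESeq2 782, 139 and 9. With only the compared groups in the fit the counts were 810 for IL-13 at 24 h, 1586 for IL-17A at 24 h, 2877 for LIGHT over IL-13, 5339 for LIGHT over IL-17A, 27 and 48 for the 24 h interactions with IL-13 and IL-17A, and 579 for the IL-13 effects of the batches. The cause was not tested.

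Without 1 library at a time, counts were within 1.5 times in 147 of 177 cases. The lowest and highest were 2675 to 3134 for LIGHT at 24 h, 1493 to 4207 for IL-13, 85 to 470 for IL-17A, 4202 to 5951 for LIGHT over IL-13, 1359 to 2545 for LIGHT over IL-17A, 38 to 226 and 1 to 5 for the interactions with IL-13 and IL-17A. In batch 2 they were 4300 to 5376 for LIGHT after PBS, 444 to 839 for IL-13, 811 to 1503 for IL-17A, 7628 to 8303 and 8844 to 9163 for LIGHT after IL-13 and IL-17A, 2835 to 3687 and 6044 to 6681 for the interactions, and 8498 to 9122 for TGFβ. They were 2136 to 2615 for the LIGHT effects of the batches, 1710 to 3055 for LIGHT after IL-17A against after IL-13, 1983 to 2624 and 3702 to 4126 for LIGHT after IL-13 and IL-17A against 24 h, 832 to 2913 for the IL-13 effects, and 10487 to 10661 for the PBS groups. Where 1 library was left in a group, it was assumed to vary like the others.

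Calls of gene lists rested on the estimated correlation between genes. With a preset correlation of 0.01 the number of lists past the threshold was 10 for LIGHT at 24 h (5 with the estimate), 9 for IL-13 (1), 13 for IL-17A (4), 11 for LIGHT over IL-13 (4), 13 for LIGHT over IL-17A (5), and 11 and 10 for the interactions with IL-13 and IL-17A (0 and 0). It was 12 for LIGHT after PBS (0), 8 for IL-13 for 72 h (0), 6 for IL-17A for 72 h (1), 12 and 11 for LIGHT after IL-13 and IL-17A (3 and 3), 10 and 7 for the interactions (4 and 0), and 11 for the LIGHT effects of the batches (6). It was 1 for LIGHT after IL-17A against after IL-13 (0), 7 and 4 for LIGHT after IL-13 and IL-17A against 24 h (0 and 0), 5 for the IL-13 effects (2), and 13 for the PBS groups (3). A replicate block gave 0 lists for IL-17A for 72 h and RLE 0 for LIGHT after IL-17A, and DESeq2 170 shared calls for IL-17A at 24 h and 72 h. The cause was not tested.

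Of results for named genes, 1898 of 1905 kept their direction and side of the threshold with RLE, 1829 without the filter, 1869 with the block, 1813 of 1836 by DESeq2, 1777 of 1885 with only the compared groups and 14834 of 16105 without 1 library, and 0 reversed. Residuals of libraries with the same replicate number correlated at −0.01 in batch 1 and 0 in batch 2 on average, so the replicates were not treated as paired. Comparisons of TGFβ with PBS by gene and of LIGHT between TGFβ and PBS were not run. In a self-test with known 1.5-fold changes edgeR recovered 59.7% at 24 h and 65.67% in batch 2, against 93.94% and 96.97% of 4-fold changes.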

Other observations

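The comparison of the PBS groups below was chosen after the data were seen. PBS for 96 h and for 24 h came from different batches, so batch and time in culture cannot be told apart. The smooth muscle actin gene ACTA2 was higher at 96 h by 3.15 ± 0.06, ELN by 6.93 ± 0.14, TNC by 3.72 ± 0.08, POSTN by 3.45 ± 0.08, ICAM1 by 2.86 ± 0.10 and COL1A1 by 1.69 ± 0.09 (10090 ± 1217 to 32660 ± 2420 CPM). These CPM were scaled over the libraries of both batches, so they differ from the values scaled within a batch given above. Of 29 other extracellular matrix genes 26 were higher and 3 lower (adjusted p = 0.0328), of 17 unfolded protein response genes 17 were higher (adjusted p = 0.0328), of 21 collagen chains 17 were higher and 3 lower (adjusted p = 0.202), and of 18 contractile genes 16 were higher and 1 lower (adjusted p = 0.0696). Of 8 pericyte and smooth muscle markers 5 were higher and 0 lower (adjusted p = 0.0393). In all 11220 genes passed, 5630 higher and 5590 lower.

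RN7SL2 was at 543.6 CPM in replicate 3 of PBS then LIGHT and at 2.598 to 22.7 CPM in the 17 other libraries of batch 2. MALAT1 was at 1049 CPM in replicate 1 of IL-13 at 24 h and at 519.7 and 432.8 CPM in the others of that group.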
